A study of Mus musculus with 6 samples.

How the data were processed

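RNA sequencing was done on cultured primary hepatocytes from mice on a B6CBAF1 background, per the labels' protocols. The 6 libraries fall into 2 groups of 3. WT animals carried no transgene, and Alb/MDA-9 animals expressed human MDA-9/SDCBP, a scaffold protein also called syntenin, with an HA tag at its C terminus, from the albumin promoter and enhancer, which are active in hepatocytes. WT and heterozygous transgenic littermates were bred for the study, were fed regular chow, and their hepatocytes received no treatment. The labels number the libraries of each group 1 to 3, without saying that these came from separate animals or cultures, so the p-values measure the spread between these libraries, part of which may be technical.

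Libraries were made with a TruSeq RNA kit, sequenced on a HiSeq3000 in repeated rounds and pooled, per the labels' protocols. FastQC 0.11.2, Trim Galore 0.6.6, STAR 2.7.9a and edgeR 3.18.1, and the builds mm10 and GRCm38, are named in the submitters' processing notes. The annotation release and the options used are not given in the sources used here. Each deposited table holds STAR's raw read counts per gene, not normalised, with 1 column for reads of either strand and 1 for each strand. STAR counts only reads aligned to a single place and a single gene, and the first 4 rows of each deposited table hold the counts of unmapped reads, reads mapped to several places, reads outside genes and reads that overlap several genes. These 4 rows were left out of library sizes and tests. Of all reads, unmapped reads were 9.67% ± 0.664 (SD, n = 3) in WT and 9.39% ± 0.162 (SD, n = 3) in Alb/MDA-9. Reads mapped to several places were 20.1% ± 0.175 and 19.3% ± 0.586, reads outside genes 5.34% ± 0.594 and 5.12% ± 0.133, and reads over several genes 0.820% ± 0.0178 and 0.811% ± 0.0221. Genes whose reads are shared with a near-identical copy can therefore lose counts, and an allele that differs from the reference can move them between copies.

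A rule set before the data were examined chose the count column. A stranded column was to be used if it held over 80% of the reads of both stranded columns, and the reverse-strand column held 97.1% in the median library. Reads on the annotated strand of genes were 16403918 to 19046739 per library. A gene with 0 reads in a library could therefore have been present at up to 0.158 to 0.183 CPM (normalised read counts scaled to library size), the level of 3 reads; such limits and the intervals given for single counts cover counting error only, since the reads carried no molecular identifiers.

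Gene names and coordinates came from GENCODE M21 on GRCm38, which held 55141 of the 55487 gene identifiers in the deposited tables. Older gene symbols were looked up in a RefSeq gene table. Genes were filtered with filterByExpr at its minimum count of 10, which left 13296 genes, and scaled by TMM factors. These were 1.04 ± 0.00815 in WT and 0.965 ± 0.0237 in Alb/MDA-9 (SD, n = 3). The difference between genotypes was tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) without covariates and with 4 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Values printed per group are means of TMM-scaled CPM with the SD over 3 libraries, and log2 changes are those of the edgeR model, Alb/MDA-9 over WT, with their SE. Data were simulated for the same 13296 genes, with 200 of them changed. In a single draw the test recovered 55.2% of genes changed 1.5-fold, 73.1% of genes changed 2-fold and 97.0% of genes changed 4-fold. The share of false calls over 10 draws was 8.43%, above the nominal level. The real data gave 1920 changed genes, and the adjusted p depends on how many genes change. These shares therefore do not give the recovery or false calls of the real comparison.

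The 35 gene lists, the tests of genes and lists between the genotypes, their alternative settings and the rule for named genes were fixed before the data were examined. Other tests were chosen afterwards, namely those of gene positions and of genes read almost only in a single genotype. So were those of cell-cycle genes against Kupffer, endothelial and stellate markers and of near-identical copies. Tests of opposite-strand reads against overlapping genes, and of the number of changed genes over other splits of the libraries, were chosen afterwards too. The setting without the clustered windows was also chosen then. The lists covered hepatocyte functions, signalling and stress pathways, markers of other liver cell types, liver zonation, sex-biased genes and read-quality classes. The 33 lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists. The camera test with a correlation estimated for each list, and fry, which tests whether the genes of a list move without comparing them with other genes, were alternatives. On simulated data 0 of the unchanged lists were called and the shifted list was found. The genes were drawn independently of each other there, so this does not check the preset correlation.

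The genes named were Sdcbp, the 6 with the largest positive and the 6 with the largest negative log2 change, and up to 4 members of each list with the smallest p past the threshold. The 12 extremes were taken among genes past the threshold with a mean log2 CPM of at least 1, a gene symbol other than a placeholder name, and no overlap between the libraries of both groups. Where fewer than 2 members of a list passed, up to 2 with the highest CPM were named, and the sex chromosome genes were named in full. The rule gave 126 genes, 117 of them past the threshold. Of the 126, 12 match transcripts of another annotated gene with at least 97% identity over at least 200 bases and 50% of the length (blastn 2.17.0), called near-identical copies here, and their counts are uncertain. Matches that overlap the named gene on the genome were not left out, so some may not be separate copies. The search of named genes also missed Gm13394, a copy of Gapdh.

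Alternatives were other scaling factors, no or stricter low-count filters, the other count columns, DESeq2 1.42.0, limma-voom with quality weights, the edgeR exact test, a test against a fold change of 1.5, genes above 1% of a library left out, each library left out in turn, and the replicate number as a block. Positions of changed genes were tested in windows of 10 Mb with at least 10 tested genes, by a hypergeometric test and 1000 permutations of the genes. Both take the genes as independent of each other. Permutation tests between sets of genes used 100000 resamples in scipy 1.17.1. The human transgene is not part of the mouse reference, so its own transcript was not measured. Reads were not analysed here, and therefore neither sequence variants nor the strain origin of any gene could be read from the data.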

Results

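Gene expression was measured by RNA sequencing in untreated, cultured primary hepatocytes of WT mice and of Alb/MDA-9 littermates, which express human MDA-9/SDCBP (syntenin, a scaffold protein that binds syndecans) in the liver. Each group had 3 libraries. Reads on the annotated strand of genes numbered 18967611, 18897555 and 16403918 in WT 1 to 3 and 19046739, 18077006 and 16756725 in Alb/MDA-9 1 to 3. The single comparison the design gives is between the genotypes. Parental-strain segments shared by a group, or a different cell make-up of the cultures, cannot be told apart in it from an effect of the transgene on hepatocytes. The genotypes parted on the first principal component, which held 55.5% of the variance, and Alb/MDA-9 3 stood apart from the other libraries on the second, which held 16.98%.

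Of 13296 genes tested, 977 were higher and 943 were lower in Alb/MDA-9, together 1920 genes or 14.4% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among changes of at least 2-fold the falls outnumbered the rises, with 351 genes lower and 131 higher, and among those of at least 4-fold 123 were lower and 33 higher. With the stricter low-count filter the 2-fold counts were 114 lower and 61 higher, and with the test against a fold of 1.5 they were 146 and 72. The libraries of both groups did not overlap for 4466 genes (33.6%, where chance gives 10%) and for 1910 of the 1920 changed genes. The split into higher and lower depended on scaling. With library totals alone 525 genes were higher and 1622 lower, with upper-quartile factors 722 and 1087, and library totals shifted the median log2 change of all genes by -0.10 against TMM. The number of changed genes fell to 1168 without WT 1, 1018 without WT 2 and 1131 without Alb/MDA-9 2. A test against a fold of 1.5 called 240 genes, 84 higher and 156 lower.

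**Figure D1:**
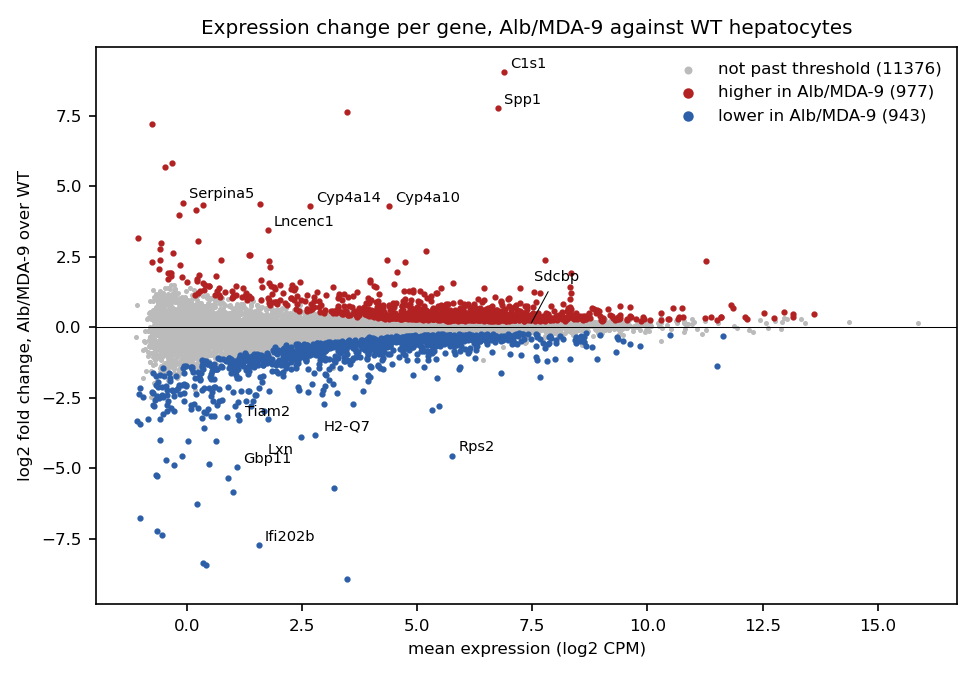
Log2 fold change of each tested gene (vertical axis, Alb/MDA-9 over WT) against its mean log2 CPM (horizontal axis); each point is 1 gene, red points are the 977 higher genes, blue points the 943 lower genes and grey points the genes that did not pass adjusted p 0.05. Named points are Sdcbp and, among genes that meet the naming rule, the 6 largest rises and 6 largest falls.

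The mouse gene Sdcbp (ENSMUSG00000028249, chromosome 4, 6365650 to 6408423 on GRCm38), the endogenous counterpart of the transgene, did not pass the test. It had 172 ± 6.94 CPM in WT and 175 ± 5.66 CPM in Alb/MDA-9 (SD, n = 3), a log2 change of 0.02 (SE 0.07, edgeR adjusted p = 0.863). The transgene is human and the reads were aligned to the mouse genome, so this value does not check the genotype labels.

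Among genes taken by the naming rule, which leaves out placeholder names and genes of low expression, the largest rise was in C1s1 (ENSMUSG00000038521, chromosome 6, 124530345 to 124542359), which encodes a complement C1s protease. It went from 0.433 ± 0.461 CPM in WT to 237 ± 24.4 CPM in Alb/MDA-9 (SD, n = 3), a log2 change of 9.04 (SE 0.25, edgeR adjusted p = 4.6e-10). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes the secreted glycoprotein osteopontin, rose from 0.967 ± 0.343 to 215 ± 56.6 CPM (log2 change 7.77, SE 0.24). The serine protease inhibitor gene Serpina5 rose from 0.262 ± 0.0881 to 5.65 ± 1.23 CPM, and the long noncoding RNA gene Lncenc1 from 0.548 ± 0.0963 to 6.11 ± 0.915 CPM. The neighbouring genes Cyp4a14 and Cyp4a10 on chromosome 4, which encode fatty acid hydroxylases and are known targets of PPAR-alpha, rose by log2 4.30 (SE 0.31) and 4.29 (SE 0.17). Cyp4a10 went from 2.03 ± 0.652 to 40.2 ± 3.26 CPM, with a near-identical copy, Cyp4a32, that could share reads. Spp1 overlaps the annotated gene Gm42793, and this gene changed by at least 2-fold too.

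By the same rule the largest fall was in Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), an interferon-inducible gene, with 311 reads over the 3 WT libraries and 1 read over the 3 Alb/MDA-9 libraries. The ratio was 287, with a 95% counting interval of 51.1 to 11370. Gbp11, a guanylate-binding protein gene annotated as a polymorphic pseudogene, fell from 3.77 ± 0.911 to 0.114 ± 0.111 CPM. The MHC class I gene H2-Q7 fell from 12.5 ± 1.58 to 0.883 ± 0.340 CPM, and Lxn, which encodes the carboxypeptidase inhibitor latexin, from 10.04 ± 0.926 to 0.671 ± 0.230 CPM. Tiam2, which encodes a Rac exchange factor, fell from 3.67 ± 0.268 to 0.370 ± 0.300 CPM. Rps2, a ribosomal protein gene, fell from 104 ± 9.61 to 4.43 ± 0.0979 CPM (log2 change -4.55, SE 0.11), and its counts are uncertain because 16 near-identical copies exist. Over all genes of the tables, 20 had at least 1 CPM in every library of one genotype and there at least 8 times the CPM, after adding 0.1, that any library of the other had, 8 of them higher in Alb/MDA-9 and 12 in WT. The 20 include the processed pseudogenes Gm8420, Gm10704, Gm15772, Gm3375, Gm6166, Gm30155 and Gm6304, and Rps2 with its near-identical copies. Among windows of 10 Mb, which like the count of these 20 genes were examined only after the data had been seen, those on chromosome 5 from 100 to 110 Mb and on chromosome 6 from 120 to 130 Mb held more genes changed at least 2-fold than the tested genes as a whole. They held 12 of 69 genes (17.4%, hypergeometric test, adjusted p = 0.00153) and 13 of 96 (13.5%, adjusted p = 0.00519), against 3.63% of all tested genes. C1s1 lies in the chromosome 6 window, and Spp1 and Gbp11 lie in the chromosome 5 window.

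Cell-cycle genes were lower in Alb/MDA-9. Of 23 measured members of the proliferation list, 20 fell and 0 rose, with a median log2 change of -1.12. The proliferation marker Mki67 fell from 20.8 ± 0.588 to 3.19 ± 2.29 CPM (SD, n = 3; log2 change -2.71, SE 0.31, edgeR adjusted p = 0.000105). The cyclin gene Ccna2, which acts in S phase and G2, fell from 10.03 ± 1.64 to 2.05 ± 0.545 CPM, the G1 cyclin gene Ccnd1 from 14.1 ± 1.36 to 3.54 ± 1.39 CPM, and the mitotic kinase gene Cdk1 from 12.02 ± 1.93 to 3.72 ± 0.710 CPM. Mki67, which has a near-identical copy, stood at 5.84 CPM in Alb/MDA-9 3 against 1.88 and 1.86 in the other Alb/MDA-9 libraries. The list differed from other genes by camera (adjusted p = 3.45e-16), and not with an estimated correlation (adjusted p = 0.252 with an estimated correlation). Adjusted over the list alone, 20 members fell and 0 rose. With the stricter low-count filter 14 of 16 members fell, and the median was -0.635.

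Markers of other liver cell types were lower in the same libraries. Of 18 markers of Kupffer cells, the resident macrophages of the liver, 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median log2 change of -0.65 (camera adjusted p = 2.56e-08). The scavenger receptor gene Marco fell from 22.9 ± 2.09 to 7.17 ± 1.33 CPM, Cd5l from 16.3 ± 1.002 to 6.72 ± 0.932 CPM and the complement receptor gene Vsig4 from 8.06 ± 0.684 to 3.62 ± 0.922 CPM. Of 19 stellate cell and fibroblast markers 9 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.50, camera adjusted p = 2.75e-05), among them the proteoglycan genes Dcn, from 88.5 ± 0.925 to 52.9 ± 2.85 CPM, and Bgn, from 26.9 ± 1.57 to 13.8 ± 1.13 CPM. Of 18 endothelial markers 7 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.33, camera adjusted p = 0.00262), among them the hyaluronan receptor gene Lyve1, from 51.9 ± 7.88 to 27.6 ± 4.11 CPM, and Eng, from 21.8 ± 2.81 to 11.9 ± 1.40 CPM. With an estimated correlation these lists gave adjusted p = 0.253 for Kupffer cells, 0.238 for stellate cells and 0.252 for endothelial cells. Kupffer markers that fell numbered 7 without WT 1, WT 2 or Alb/MDA-9 2. Stellate markers numbered 3, 4 and 5 without WT 1, 2 and 3, and endothelial markers 4 without Alb/MDA-9 2, while 1 endothelial marker rose without Alb/MDA-9 3.

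Other marker lists of non-hepatocyte cells did not pass with the filter and libraries used. Of 6 neutrophil and monocyte markers 1 fell, Plac8, also when adjusted over the list alone (camera adjusted p of the list 0.103, 0.0402 without WT 1; directional fry adjusted p = 0.0294), a call that ended without WT 1, WT 3 or Alb/MDA-9 2. Plac8 lies in the chromosome 5 window. Without Alb/MDA-9 1, without a low-count filter or with voom and quality weights, 2 markers fell, and Itgam had 1.74 ± 0.341 and 1.38 ± 0.275 CPM. Of 9 cholangiocyte and mesothelial markers 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.911). With the stricter low-count filter 6 of them were tested, 3 rose and 1 fell, and the list passed as higher (median 0.38, camera adjusted p = 0.0434). Spp1 and the transcription factor gene Sox9 rose, the latter from 33.4 ± 4.15 to 57.9 ± 1.15 CPM, and the mesothelial gene Msln and the keratin gene Krt7 fell, from 5.81 ± 1.23 to 0.614 ± 0.671 CPM and from 6.22 ± 2.04 to 1.91 ± 0.861 CPM. None of the lymphocyte markers had enough reads to be tested (0 of 17), and of the red blood cell markers 1 was tested, the heme synthesis gene Alas2, at 36.6 ± 3.58 and 28.9 ± 1.55 CPM (edgeR adjusted p = 0.0304). The Alas2 call ended without WT 1, WT 3 or Alb/MDA-9 2.

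Inflammatory genes under NF-kB control were higher in Alb/MDA-9. Of 20 measured members 13 rose and 0 fell, with a median log2 change of 0.47 (camera adjusted p = 4.48e-08; adjusted p = 0.252 with an estimated correlation). The monocyte chemokine gene Ccl2 rose from 121 ± 1.06 to 284 ± 18.3 CPM (SD, n = 3; log2 change 1.23, SE 0.07, edgeR adjusted p = 3.33e-07), the chemokine gene Cxcl10 from 7.74 ± 1.34 to 23.4 ± 6.74 CPM, the NF-kB feedback inhibitor gene Tnfaip3 from 77.8 ± 3.67 to 147 ± 11.8 CPM, and Nfkb1, which encodes an NF-kB subunit, from 71.2 ± 4.01 to 116 ± 6.05 CPM. Adjusted over the list alone, 13 members rose and 0 fell, and without Alb/MDA-9 3 1 member fell. Kupffer cell markers were lower in these libraries.

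Of 20 acute phase genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.33 (camera adjusted p = 0.00164; adjusted p = 0.472 with an estimated correlation). Those that rose include the plasma protein genes Hp, from 2649 ± 248 to 4525 ± 424 CPM, Fgl1, from 503 ± 53.8 to 844 ± 86.7 CPM, and Hpx, from 7790 ± 139 to 10670 ± 1018 CPM. Hamp, which encodes the iron hormone hepcidin, fell from 23.8 ± 3.24 to 6.28 ± 4.08 CPM. The number that rose was 5 without WT 2, and the number that fell was 1 without WT 1. Of 23 interferon response genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.968), with Stat2 higher, from 162 ± 4.43 to 209 ± 6.5 CPM, and the chemokine gene Cxcl9 higher, from 23.2 ± 0.406 to 42.6 ± 13.9 CPM. Interferon genes that rose numbered 2, 3 and 2 without WT 2, WT 3 and Alb/MDA-9 2. Those that fell numbered 0 without WT 1 and 1 without WT 2, WT 3 or Alb/MDA-9 2.

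Genes of the urea cycle and amino acid breakdown were lower in Alb/MDA-9. Of 18 members 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median log2 change of -0.33 (camera adjusted p = 4.81e-05; adjusted p = 0.390 with an estimated correlation). Tat, which encodes tyrosine aminotransferase, fell from 77.1 ± 7.69 to 10.99 ± 7.28 CPM (SD, n = 3; log2 change -2.80, SE 0.30, edgeR adjusted p = 7.82e-05), and Hpd, the next enzyme of tyrosine breakdown, from 89.1 ± 9.88 to 33.3 ± 9.77 CPM. Cps1, which encodes the first enzyme of the urea cycle, fell from 171 ± 5.88 to 88.4 ± 11.3 CPM, and Ass1, which has a near-identical copy, from 81.8 ± 7.06 to 48.6 ± 6.68 CPM. The median was -0.21 with the stricter low-count filter. Tat had 18.8, 9.67 and 4.46 CPM in Alb/MDA-9 1, 2 and 3, Hpd 42.6, 34.2 and 23.1, and Ass1 55.47, 48.04 and 42.15. These were lowest in Alb/MDA-9 3, whereas Cps1 had 101.4, 81.12 and 82.73 CPM.

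Of 20 glycolysis and gluconeogenesis genes 3 rose and 4 fell (3 and 5 adjusted over the list alone), without a call for the list (camera adjusted p = 0.911). Pck1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, fell from 13.3 ± 3.48 to 1.99 ± 1.25 CPM. The hepatocyte glucose transporter gene Slc2a2 fell from 67.4 ± 4.65 to 19.2 ± 7.87 CPM. In Alb/MDA-9 1, 2 and 3, Pck1 had 3.149, 2.155 and 0.6623 CPM and Slc2a2 26.3, 20.44 and 10.72 CPM. Pklr, which encodes liver pyruvate kinase, rose from 74.4 ± 3.27 to 119 ± 14.2 CPM, and Gapdh, which has near-identical copies, fell from 31.7 ± 1.81 to 20.9 ± 0.875 CPM. The processed pseudogene Gm13394, 99.9% identical to Gapdh over 1000 bases, held 656 CPM in WT and 298 CPM in Alb/MDA-9. The Gapdh counts therefore do not give the level of its transcript. The count of 3 rises was 1 without any single one of the libraries WT 1, WT 2, WT 3, Alb/MDA-9 1 and Alb/MDA-9 2, 1 with library totals, upper-quartile factors or the replicate block, and 6 without Alb/MDA-9 3.

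Cholesterol synthesis genes were higher in Alb/MDA-9 by small amounts. Of 21 members 10 rose and 0 fell over all genes, with a median log2 change of 0.22 (camera adjusted p = 5.48e-05; adjusted p = 0.497 with an estimated correlation). Adjusted over the list alone, 12 rose and 1 fell. Cyp51 rose from 392 ± 7.44 to 551 ± 27.4 CPM, Pmvk from 67.5 ± 3.51 to 95.8 ± 14.0 CPM and Fdps from 16.8 ± 2.49 to 25.9 ± 2.77 CPM, all of them enzymes of the pathway. The number of rises fell to 5, 3 and 3 without WT 1, 2 and 3 and to 4 without Alb/MDA-9 2; 1 member fell without Alb/MDA-9 3, and the rises numbered 3 with library totals (median 0.12), 5 with upper-quartile factors or the replicate block and 6 with the stricter low-count filter. With library totals, without a low-count filter and with voom and quality weights 1 member fell.

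Bile acid genes were lower on balance. Of 15 members 6 fell and 1 rose (6 and 1 adjusted over the list alone; median log2 change -0.31, camera adjusted p = 0.0160; adjusted p = 0.565 with an estimated correlation). The canalicular bile salt pump gene Abcb11 fell from 50.4 ± 0.718 to 28.1 ± 2.75 CPM, the phospholipid transporter gene Abcb4 from 18.6 ± 0.293 to 10.8 ± 1.77 CPM and the uptake transporter gene Slco1b2 from 22.3 ± 1.82 to 8.67 ± 4.76 CPM. Cyp7b1, an enzyme of the alternative bile acid pathway, rose from 25.4 ± 2.12 to 36.6 ± 5.68 CPM. The call of the list ended without Alb/MDA-9 3 (median -0.21, camera adjusted p = 0.156), where 2 members rose.

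Of 12 tested genes expressed around the central vein 3 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.20, camera adjusted p = 0.0202; adjusted p = 0.497 with an estimated correlation), among them Cyp1a2, from 67.6 ± 5.65 to 43.0 ± 3.21 CPM. This call too ended without Alb/MDA-9 3 (median -0.06, camera adjusted p = 0.0893), and the falls numbered 1 without WT 1 or WT 2, with 1 rise without Alb/MDA-9 1 or without a low-count filter. The median was -0.31 with library totals, where 5 fell, -0.32 without a low-count filter and -0.33 with the stricter one. Of 16 periportal genes 5 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.911), with Hsd17b13, a lipid droplet enzyme gene inside the chromosome 5 window, higher, from 70.6 ± 5.31 to 366 ± 77.2 CPM.

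Genes under control of NRF2, a regulator of the oxidative stress response, were lower. Of 20 members 8 fell and 0 rose, with a median log2 change of -0.22 (camera adjusted p = 0.000373; adjusted p = 0.252 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. The sulfiredoxin gene Srxn1 fell from 554 ± 37.2 to 339 ± 28.9 CPM, the cystine transporter gene Slc7a11 from 70.6 ± 2.27 to 45.9 ± 4.36 CPM and Ugdh from 499.5 ± 33.1 to 314 ± 69.2 CPM. The falls numbered 4, 4 and 5 without WT 1, 2 and 3 and 5 without Alb/MDA-9 2, and 1 member rose without Alb/MDA-9 3, without a low-count filter or with voom and quality weights. Of 7 tested mitochondrially encoded genes 3 rose and 0 fell, 4 and 0 adjusted over the list alone (median 0.30, camera adjusted p = 0.00262; adjusted p = 0.526 with an estimated correlation), with mt-Nd5, a subunit of respiratory complex I, from 10440 ± 873 to 14500 ± 608 CPM. The rises numbered 1 without WT 1, WT 2 or Alb/MDA-9 2 and 7 without Alb/MDA-9 3, and the median was 0.19 with library totals. Mitochondrial reads were 6.29% ± 0.154 of the gene reads in WT and 6.93% ± 0.771 in Alb/MDA-9 (SD, n = 3).

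**Figure D2:**
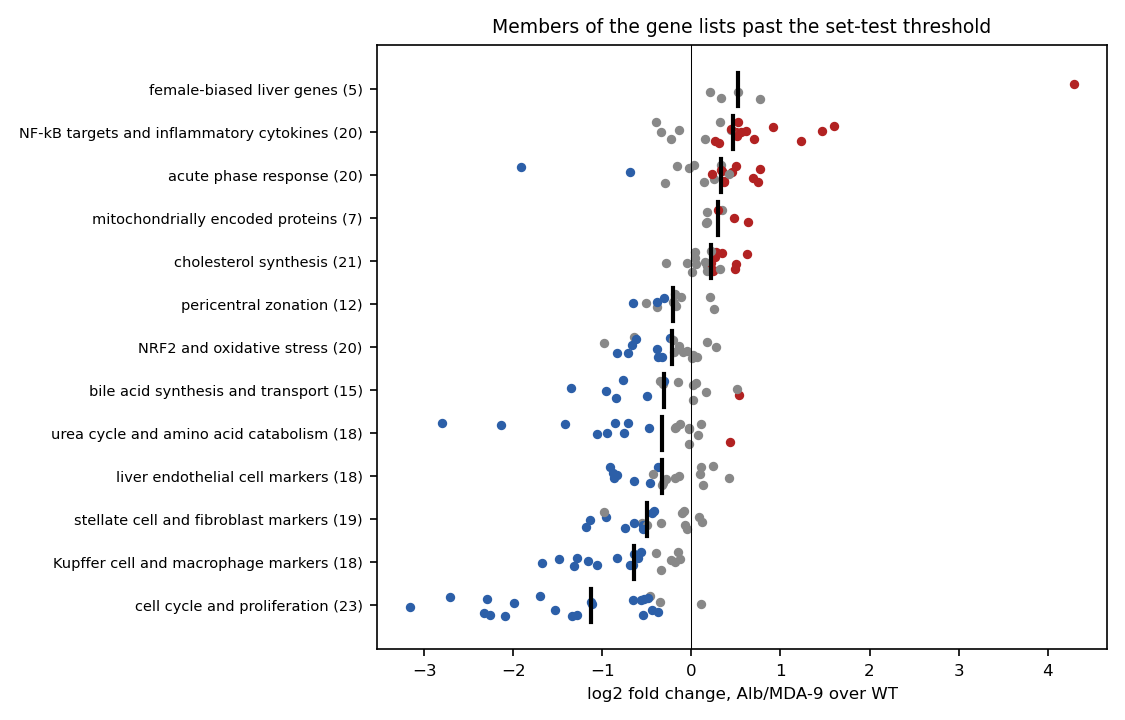
Log2 fold change (horizontal axis, Alb/MDA-9 over WT) of each tested member of the 13 gene lists past the camera threshold, with the number of tested members after each name; red and blue points passed adjusted p 0.05 as higher and lower, grey points did not, and black bars mark the medians. The cell-cycle list has the lowest median, at -1.12.

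Hepatocyte identity genes moved both ways. Of 22 members 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.617). The transcription factor gene Prox1 rose from 61.9 ± 3.99 to 95.3 ± 9.55 CPM and the transferrin gene Trf, which has a near-identical copy, from 6449 ± 177 to 9481 ± 514 CPM. The nuclear receptor genes Nr1h4 and Nr1i3, which encode FXR and CAR, fell from 52.6 ± 1.78 to 39.2 ± 2.75 CPM and from 1.69 ± 0.490 to 0.244 ± 0.269 CPM. The rises numbered 9 without Alb/MDA-9 3 and 7 with voom and quality weights, and the falls 4 there and with library totals and 1 with the stricter low-count filter. Of 20 cytochrome P450 genes 5 rose and 4 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.911). Cyp4a10 and Cyp4a14 rose, while Cyp1a2 and Cyp2c29 fell, the latter from 251 ± 22 to 172 ± 25.7 CPM. The P450 rises numbered 3, 2, 3 and 2 without WT 1, WT 2, Alb/MDA-9 1 and Alb/MDA-9 2, and the falls 7 and 2 without Alb/MDA-9 1 and 2. With library totals 3 P450 genes rose, and 7 fell with library totals, upper-quartile factors, no low-count filter or voom and quality weights.

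Neither list of fatty acid genes passed. Of 21 genes of fatty acid synthesis and storage 2 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.911), with the lipid droplet gene Plin2 higher, from 438 ± 19.7 to 690.3 ± 94.1 CPM, and Dgat2, which makes triglycerides, lower, from 48.7 ± 1.67 to 37.9 ± 1.06 CPM. Of 18 genes of fatty acid oxidation 2 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.914). Without WT 1, WT 2 or Alb/MDA-9 2 the storage genes counted 1 rise and 1 fall, and without WT 3 1 fall, and the storage falls numbered 4 with library totals. The oxidation rises numbered 0 without any single one of WT 1, WT 2, WT 3 and Alb/MDA-9 2, 0 with upper-quartile factors or library totals, 1 with unstranded counts or the replicate block and 4 with voom and quality weights, and the falls 1 without WT 1 or WT 2 and 5 without Alb/MDA-9 3.

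The lists of integrins and of exosome genes, which hold known partners of MDA-9, gave no call. Of 22 integrin, syndecan and focal adhesion genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; median log2 change 0.12, camera adjusted p = 0.0659). The list passed without Alb/MDA-9 1 (adjusted p = 0.0293), without Alb/MDA-9 2 (adjusted p = 0.0349) and without a low-count filter (adjusted p = 0.0211). Itga2 rose from 42.5 ± 3.02 to 80.02 ± 9.59 CPM and Itgav from 294 ± 13.1 to 385 ± 17.6 CPM, while Itgb3 fell from 33.6 ± 3.34 to 18.0 ± 1.04 CPM and Itga3 from 279.9 ± 14.7 to 188 ± 26.9 CPM. Of 19 genes for exosome formation and syntenin partners 2 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.483), with the phospholipase gene Pld2 higher, from 33.3 ± 0.199 to 43.0 ± 1.70 CPM. The exosome falls numbered 0 without WT 1, WT 3 or Alb/MDA-9 2 and 1 without WT 2 or Alb/MDA-9 1, and the rises 1 without WT 3 and 4 without Alb/MDA-9 3. With library totals 1 exosome gene rose and 4 fell, and 1 fell with the stricter low-count filter or without the clustered windows.

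Of 20 angiogenesis genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.914). Angpt2, which encodes a ligand of the endothelial receptor TIE2, fell from 44.2 ± 3 to 19.7 ± 3.09 CPM, and the matricellular genes Thbs1, Ccn1 and Ccn2 rose, from 209.7 ± 12.1 to 367 ± 35.8, from 252 ± 12.3 to 395 ± 11.1 and from 1157 ± 33.7 to 1854 ± 198 CPM. Of 21 genes of epithelial-mesenchymal transition and matrix remodelling 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.968), with Vim higher, from 575 ± 3.87 to 786 ± 81.6 CPM, and the matrix genes Sparc and Timp1 lower, from 37.1 ± 1.35 to 22.8 ± 4.98 and from 16.4 ± 2.58 to 8.98 ± 2.21 CPM. Markers of endothelial and stellate cells were lower in these libraries. Of 14 progenitor and tumour-associated genes 5 rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.914). Beside Spp1 and Sox9, the fetal liver gene Afp fell from 13.0 ± 0.988 to 6.18 ± 0.878 CPM and Ly6d from 128 ± 15.8 to 69.1 ± 5.04 CPM. The progenitor rises numbered 3 without WT 1.

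Stress lists other than NRF2 gave no call. Of 20 unfolded protein response genes 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.202), with the chaperone gene Dnajb9 lower, from 54.7 ± 2.63 to 34.9 ± 7.14 CPM; the falls numbered 1 without WT 2 or Alb/MDA-9 2 and 5 without Alb/MDA-9 3, and the rise was lost without WT 1, WT 2, WT 3, Alb/MDA-9 2 or Alb/MDA-9 3 and numbered 2 without Alb/MDA-9 1 or with voom and quality weights. The rise was also lost with upper-quartile factors and the stricter low-count filter. With library totals the list passed as lower (median -0.21, camera adjusted p = 0.0460), with 0 rises and 5 falls. Of 22 immediate early genes, which also respond to tissue dissociation, 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.617), with Egr1 higher, from 241 ± 7.71 to 396 ± 39.4 CPM, and Junb higher, from 131 ± 24.0 to 203 ± 8.05 CPM. The falls numbered 1 without WT 1 and 0 without WT 2 or Alb/MDA-9 2. Of 18 hypoxia genes 1 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.216). Adm, which encodes the vasodilator adrenomedullin, fell from 63.4 ± 3.76 to 33.5 ± 12.1 CPM. Ndrg1 and Vegfa had 542 ± 5.02 and 453 ± 189 CPM, and 336 ± 32.3 and 317 ± 118 CPM, in WT and Alb/MDA-9, and Ndrg1 passed as lower without a low-count filter (adjusted p = 0.0105). The hypoxia list passed as lower without Alb/MDA-9 1 (median -0.28, adjusted p = 0.00490) and without Alb/MDA-9 2 (median -0.19, adjusted p = 0.0224), where 3 and 1 members fell. Without Alb/MDA-9 3 its median was 0.15 (adjusted p = 0.200), with 3 rises and 2 falls. The falls numbered 2 with upper-quartile factors or library totals, 4 without a low-count filter and 3 with the replicate block or voom and quality weights, with 2, 1 and 2 rises in these last 3 settings.

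Of 24 cytosolic ribosomal protein genes 0 rose and 2 fell (0 and 2 adjusted over the list alone), Rps2 and Rps18, both with near-identical copies. The list's median log2 change was 0.08 and its mean -0.15, it did not pass with camera (adjusted p = 0.779), and fry gave a lower direction (adjusted p = 0.0472). Without Alb/MDA-9 1 or 3, or without a low-count filter, 1 member rose. Rps18 fell from 26.6 ± 1.67 to 9.80 ± 1.59 CPM.

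Of 20 male-biased liver genes 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.914). Serpina1e, an alpha-1-antitrypsin gene which has a near-identical copy, Serpina1a, rose from 807 ± 73.4 to 4120 ± 194 CPM, and Moxd1 fell from 23.3 ± 1.86 to 13.8 ± 0.998 CPM. Of 5 tested female-biased genes 1 rose, Cyp4a10 (2 rose and 0 fell adjusted over the list alone), and the list passed (median 0.52, camera adjusted p = 0.0229; adjusted p = 0.394 with an estimated correlation) but not without Alb/MDA-9 1 (adjusted p = 0.0735), and 2 members rose without Alb/MDA-9 3, without a low-count filter or with voom and quality weights. The median was 0.83 without WT 3. Reads of the Y-linked genes were present in all 6 libraries. Ddx3y had 98.6 ± 4.41 CPM in WT and 81.9 ± 9.62 in Alb/MDA-9, Eif2s3y 75.7 ± 1.27 and 66.9 ± 11.01, Uty 22.4 ± 1.24 and 23.8 ± 0.857, and Kdm5d 28.7 ± 2.52 and 28.1 ± 1.34, with none of these 4 genes past the threshold (edgeR adjusted p from 0.0633 to 0.871). Eif2s3y passed as lower without Alb/MDA-9 1, as did Ddx3y, and Ddx3y also with upper-quartile factors, library totals, no or a stricter low-count filter, voom with quality weights and the exact test. Adjusted over the 4 tested sex chromosome genes as a list alone, 1 fell, and camera gave adjusted p = 0.586. Xist had too few reads to be tested.

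**Figure D3:**
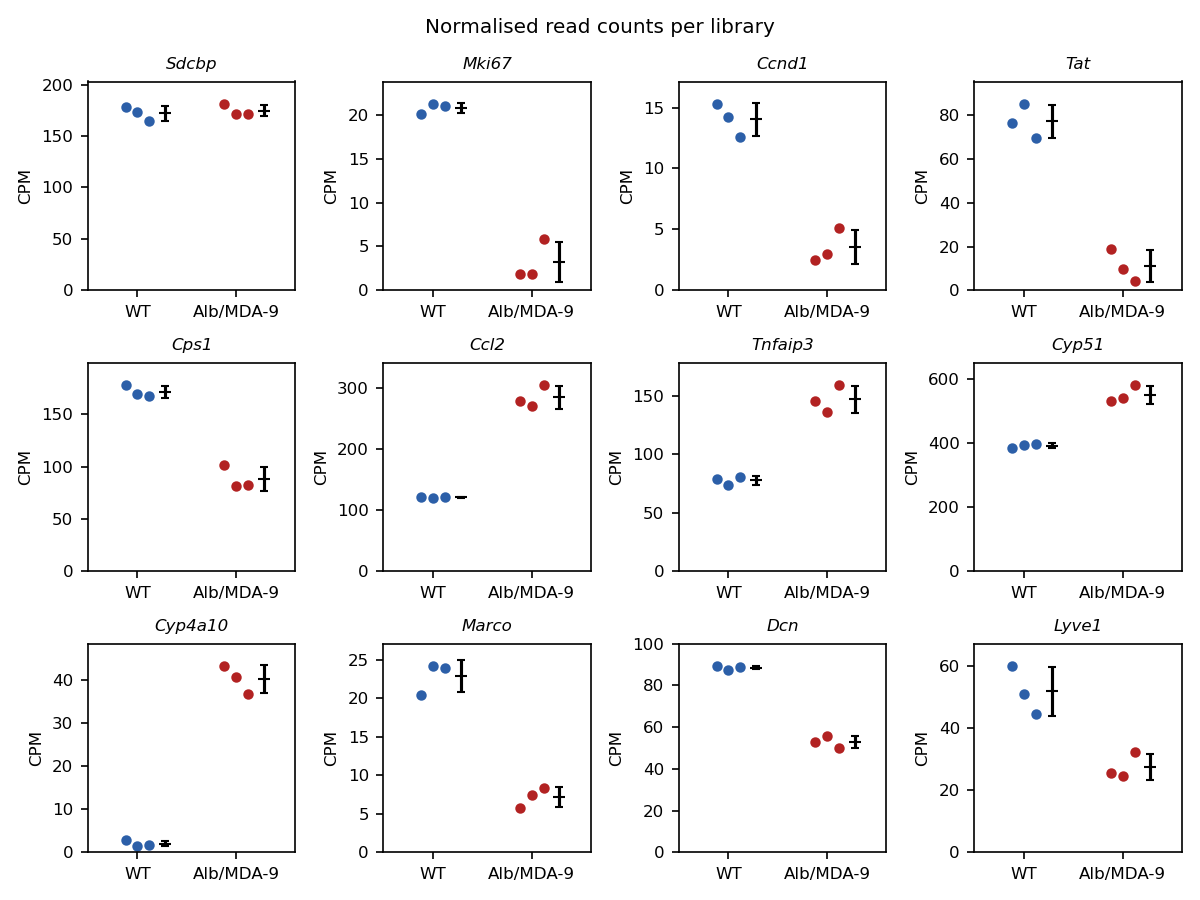
Normalised read counts (CPM, vertical axes, starting at 0) of 12 genes in each library; blue points are WT libraries, red points Alb/MDA-9 libraries, and the black marks beside them show the mean and SD of 3 libraries. The genotypes overlap for Sdcbp, and do not for the other 11 genes.

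In all, 13 of the 33 tested lists passed with the preset correlation, 5 as higher and 8 as lower in Alb/MDA-9, and 0 passed with an estimated correlation. The same camera test called 4 to 11 lists when the 6 libraries were parted in the 9 other ways, each of which mixes the genotypes. Median, mean and test differed in sign for some lists that did not pass. The median and mean log2 changes were -0.07 and 0.04 for fatty acid synthesis, 0.02 and -0.28 for glycolysis and gluconeogenesis, 0.09 and -0.01 for the exosome list, -0.19 and 0.29 for the progenitor list, 0.02 and -0.03 for immediate early genes, -0.06 and 0.18 for cholangiocyte markers and -0.02 and 0.04 for male-biased genes. Camera ranked the lists of hepatocyte identity, angiogenesis and epithelial-mesenchymal transition upward although both values were below 0, with medians of -0.0037, -0.10 and -0.03.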

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

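The comparison of opposite-strand reads with the genes on the other strand was chosen only after the result was seen. The count column of the strand opposite to the annotation, which the report's comparison does not use, held 2775 genes with enough reads to be tested. Of these, 61 differed between the genotypes, 35 higher and 26 lower in Alb/MDA-9. Among the 35, 27 were not called higher on their own strand, where 21 of them had too few reads to be tested and 6 were tested. All 27 overlap a tested gene on the other strand, 26 different genes in all, of which 24 rose there. Where several genes overlapped, the gene with the smallest p was taken, which favours changed genes. Reads of the overlapping gene on its own strand also fall in this column. A shared direction is therefore partly built in. CPM in this column are relative to its own 481757 to 578737 reads per library, so they do not compare with CPM of the annotated strand. The opposite-strand reads of Gm16567, which overlaps C1s1, went from 6.26 to 2424 CPM. The exceptions were B430119L08Rik, from 557 to 6140 CPM over Serpina1c (log2 change -0.15, edgeR adjusted p = 0.237), and Gm28731, from 54.1 to 121 CPM over Bnip2 (log2 change 0.18, edgeR adjusted p = 0.102). These genes were chosen after their values were seen.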

How the results depend on the processing

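Leaving out the genes of the clustered windows was chosen after seeing the data, and the other alternatives were fixed before. Over the alternatives other than the opposite-strand column, the 33 tested lists gave 592 values, of which 520 kept direction and side of the threshold, 21 lost the call, 8 gained it and 43 turned direction. The 125 named genes present gave 2354 values, of which 2173 kept both, 163 lost the call, 13 gained it and 5 turned direction. Of the list and gene results that turned, 0 had passed the threshold in the report, and 2 passed in the alternative, the cholangiocyte list with the stricter filter and the ribosomal list with fry. DESeq2, the exact test and the test against a fold of 1.5 gave no list values. The number of changed genes was 1018 to 2386 with 1 library left out, with 503 to 1178 higher and 515 to 1208 lower. The test against a fold of 1.5, which asks for larger changes, called 240 genes, 84 higher and 156 lower, and 79 of the 117 changed named genes lost their call there. Library totals gave 525 higher and 1622 lower genes, after a shift of the median of all genes by -0.10. Without 1 library, 22 of the 117 lost their call.

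The opposite-strand column, in which few genes have reads, called 61 genes (35 higher and 26 lower) and 1 list. There Tiam2 (0.15), Ccna2 (0.22), Ccnd1 (0.21) and Egfl7 (0.19) had the other sign from their results on the annotated strand. So had the medians of the lists of cell cycle (0.15), hepatocyte identity (0.44), angiogenesis (0.45), unfolded protein response (0.45), periportal genes (0.29) and ribosomal proteins (-0.0036). The column holds reads of the other strand, among them those of overlapping genes, so these values do not test the results on the annotated strand. The origin of these reads was not tested. Lists past the threshold numbered 11 to 15 with 1 library left out, 0 with an estimated correlation and 31 with fry for changes in either direction, which asks another question. With fry for one direction 10 lists passed, and the bile acid, cholesterol, acute phase, mitochondrial and pericentral lists lost their call (adjusted p = 0.0911, 0.0589, 0.0589, 0.112 and 0.0716), while the neutrophil and monocyte list and the ribosomal list gained one (adjusted p = 0.0294 and 0.0472). Fry took the ribosomal list, whose median is 0.079, as lower, and the interferon, progenitor and periportal lists, whose medians are -0.081, -0.19 and -0.099, as higher, where camera gave the other direction.

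The following log2 changes, or medians of lists, turned sign against the report; the cause was not tested, apart from the shift of all genes with library totals. With library totals they were Sdcbp (-0.082), Uty (-0.013) and the ribosomal (-0.024), P450 (-0.084), exosome (-0.019), glycolysis (-0.086) and immediate early (-0.082) lists. With upper-quartile factors they were Sdcbp (-0.017) and the P450 (-0.020), glycolysis (-0.020) and immediate early (-0.018) lists. With voom and quality weights they were the P450 (-0.017), fatty acid oxidation (0.0090), fatty acid synthesis (0.023) and hepatocyte identity (0.024) lists. The hepatocyte identity list turned to 0.057 with the stricter filter and 0.044 with unstranded counts, the cholangiocyte list to 0.38 with the stricter filter, and the glycolysis list to -0.031 without a filter.

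With 1 library left out, values on both sides of 0 were found for Sdcbp (-0.0077 to 0.049), Ndrg1 (-0.48 to 0.050), Vegfa (-0.31 to 0.19) and Kdm5d (-0.089 to 0.037). Among lists they were found for hepatocyte identity (-0.041 to 0.029), P450 (-0.066 to 0.10), fatty acid synthesis (-0.046 to 0.048) and oxidation (-0.067 to 0.015), glycolysis (-0.044 to 0.11), angiogenesis (-0.15 to 0.064), epithelial-mesenchymal transition (-0.088 to 0.059), immediate early (-0.067 to 0.067), hypoxia (-0.28 to 0.15), cholangiocyte (-0.21 to 0.068), periportal (-0.21 to 0.014) and male-biased genes (-0.095 to 0.056).

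With the replicate block 1601 genes changed and 13 lists passed, and the median of the P450 list turned to -0.0071. Deviations of libraries with the same number correlated at -0.0408, -8.73e-05 and -0.0619, so no pairing by number was seen. With 3 libraries per group this check cannot exclude one. At these depths and with 3 libraries per group, simulated changes of 1.5-fold were found for 55.2% of genes. Only 200 genes were changed in that simulation, far fewer than were called here, so the share in the real data may differ. Depth was not varied.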

Other observations

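All tests in this part were chosen only after the result was seen, except the count of gene lists over other splits of the libraries. The gene families in this paragraph and the next were also chosen after their values were seen. Of 13 tested Cyp2c genes, a P450 family, 6 rose and 1 fell. Cyp2c67 rose from 53.7 ± 2.08 to 107 ± 17.4 CPM (SD, n = 3) and Cyp2c68 from 9.27 ± 0.356 to 25.2 ± 4.84 CPM, while Cyp2c29 fell, in a family with near-identical members whose reads can be shared. Of 6 complement genes of the C1r, C1s and C4 families 2 rose and 3 fell. C1ra rose from 9.72 ± 0.930 to 37.6 ± 1.80 CPM, C1rb fell from 74.1 ± 1.97 to 38.2 ± 3.64 CPM, and C4b fell from 348 ± 3.16 to 159 ± 8.59 CPM.

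Of 5 tested MHC class II genes, which act in antigen presentation, 0 rose and 2 fell, with H2-Ab1 from 4.32 ± 0.617 to 0.618 ± 0.0744 CPM and H2-Aa from 2.55 ± 0.107 to 1.02 ± 0.314 CPM. In the same libraries 12 of 18 Kupffer cell markers were lower, with a median log2 change of -0.65. Of 8 guanylate-binding protein genes 1 rose and 3 fell, the most abundant of these being Gbp11, at 3.77 ± 0.911 CPM in WT. The tight-junction gene Cldn4 rose from 196 ± 13.5 to 454 ± 21.8 CPM, while Tspan8 fell from 8.34 ± 1.22 to 1.91 ± 1.61 CPM. Among hypoxia genes, Ndrg1 had 582.5, 540.3 and 236 CPM in Alb/MDA-9 1, 2 and 3, and Vegfa 408, 359.8 and 183 CPM.

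The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1920 changed genes and the highest other split 0, so that 1 of 10 splits gave as many. For gene lists past the camera threshold the real split gave 13 and the highest other split 11, again 1 of 10. Every other split mixes both genotypes. Their difference then adds to the spread within groups, which works against gene calls, and part of it stays between the groups. Neither count therefore shows what chance alone would give.

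Genes read almost only in one genotype, and the windows on chromosomes 5 and 6 rich in changed genes, form the first pattern weighed. Some of these genes are pseudogenes whose near-identical copies changed the other way. Gm6166 changed by log2 -5.71 and Fabp5 by 2.69, Gm15772 by -8.91 and Rpl26 by 0.70, and Gm3375 by 7.62 and Psmb5 by -0.36. For Gm10704 and Gm6304 the copies Rtraf and Mrpl27 did not pass. Reads shared between copies were not separated from changes of these genes. Chance placement of each changed gene, independently of its neighbours, is argued against by a permutation p of 0.002 for the smallest window p. The permutation moved genes singly, so it does not cover neighbours of a gene family, or overlapping genes, that change or share reads together. The chromosome 5 window holds Gbp4, Gbp6, Gbp10, Gbp11 and the overlapping Spp1 and Gm42793, and the chromosome 6 window holds C1s1 and C1ra. An effect of the transgene insertion site on its neighbours, as the whole cause, is argued against by on/off genes on 12 chromosomes. An insertion near either window stays open. Alleles segregating independently among animals would part the libraries in other ways too, and 1 such gene was found against 20 that part the genotypes, but the labels do not say that the libraries of a group come from separate animals, so the count does not decide and this cannot be told apart from a difference between the genotypes. What stays open too, and was not tested, is an effect of the transgene on these genes, and segments of different parental strains shared by the libraries of a group. The second is a hypothesis that may be checked on sequence variants in the reads.

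The second pattern is the lower expression of 20 cell-cycle genes, 19 of which lie outside the clustered windows (a count set by gene position that does not test an effect of the windows on genes elsewhere), beside lower Kupffer, endothelial and stellate markers. An even loss of those cells, alike for Kupffer, endothelial and stellate cells, is argued against for the list as a set. The mean log2 change of the 23 cell-cycle genes, -1.27, lay below that of the 55 pooled markers, -0.51, by -0.76. The permutation p was 2e-05, the smallest the resamples can give, and genes are not independent. Over the 16 and 40 members that pass the stricter low-count filter the difference was -0.62 (permutation p = 0.00136). The markers did not fall alike, with mean log2 changes of -0.74 for Kupffer, -0.48 for stellate and -0.32 for endothelial markers. Loss of a single cell type was not compared and stays open. For the more abundant genes the test against the pooled markers cannot decide. The difference was -0.30 over the 11 and 24 members of at least 10 CPM (permutation p = 0.159) and -0.17 over the 8 and 16 of at least 20 CPM. These limits apply to the mean CPM of both genotypes, so a fall can itself remove a gene or marker. Top2a, Ccnd1, Cdk1 and Ccna2 fell and missed the limit of 10 CPM, although each was above it in WT. Tyms, which did not pass the test, missed it too. Mki67, Ccne2 and E2f1 missed the limit of 20 CPM in the same way. The most abundant cell-cycle genes had log2 changes of 0.11 for Myc, which did not pass, -0.38 for Mcm6, -0.66 for Mcm5 and -0.44 for Pcna. The most abundant marker of each cell type did not pass, with Cd68 at 271 ± 11.5 and 248 ± 97.5 CPM, Stab1 at 54.6 ± 2.46 and 49.4 ± 3.52 CPM and Reln at 149 ± 6.69 and 138 ± 34.4 CPM in WT and Alb/MDA-9, whereas the next ones, Ecm1 (145 to 107 CPM) and Dcn of stellate cells and Cdh5 (52.9 to 38.4 CPM) and Lyve1 of endothelial cells, fell, and Cd14 and C1qa of Kupffer cells did not pass; 0 of 18 Kupffer, 0 of 18 endothelial and 1 of 19 stellate markers are in another list. A smaller share of a cycling subset of cells may account for the pattern, as may lower proliferation with the transgene, and neither was tested.

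The third pattern is that near-identical copies changed in opposite directions, as C1ra, from 9.72 to 37.6 CPM, and C1rb, from 74.1 to 38.2 CPM, whose sum went from 83.9 to 75.8 CPM. For Rps18, from 26.6 to 9.80 CPM, and Gm10260, from 109.6 to 263 CPM, the sum went from 136 to 273 CPM, which an exchange of reads between these 2 alone does not give. Reads exchanged between copies, for example where alleles differ from the reference, and separate changes of each copy cannot be told apart for the pairs as a set. Of 29 pairs with both members changed, 13 went in opposite directions (44.8%, exact 95% interval 26.5% to 64.3%), too few pairs to place the share above or below 50%, and 11 of them share a member with another pair, so the interval is too narrow. Of the 13 opposite pairs, 8 kept their summed CPM within 1.5-fold and 5 did not.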
